A study of Mus musculus with 13 samples.

How the data were processed

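Brain RNA of male Balb/c mice was sequenced in 13 libraries: 4 of the normal condition (Con), 5 after 24 h at 8000 m (Mod) and 4 after the same exposure with 6-OHG. Per the labels, RNA was extracted with Trizol and libraries were read on an Illumina NovaSeq as pairs of 150 bases. The deposited table holds FPKM, fragments scaled by gene length and by mapped fragments, computed by the authors with 1 column per library. Per the submitters' processing notes the tools were cutadapt 1.9, FastQC, HISAT2 2.2.1, StringTie 2.1.6, featureCounts 1.5.0-p3, DESeq2 and edgeR, with no role or order given. Which of them made the FPKM values is therefore unknown, as are the annotation release, the strand setting and any filter. The builds named are GRCm38 and mm10, which share their coordinates.

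The table lists 37636 gene IDs, of which 37499 were matched to symbols and 137 were not. Coordinates, exon lengths and GC content came from GENCODE M21 on GRCm38. Totals of reads are not given. Of the low values of genes with a single transcript, 2.65% to 3.38% lay at the worth of 1 read or of a pair, and the relative depth per library is a rough measure that rests on these alone. Within 0.01 of a whole multiple of that worth lay 4.22% to 6.53% of values, against 1.54% to 1.66% for other steps. Most values therefore did not give counts, and no counting error or floor is given. All 13 columns were used, and no reads were realigned.

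Groups, comparisons, lists, thresholds and a set of other settings were fixed before the data were examined. Values were taken as log2(FPKM + 1), and the 13905 genes with a mean of at least 1 FPKM over all libraries were tested. Linear models with 1 mean per group were fitted in limma 3.58.1 under R 4.3.3, with moderated variances and a trend on the mean. The comparisons were Mod against Con, 6-OHG against Mod and 6-OHG against Con. P-values were adjusted over all genes tested by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05.

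Of 49 fixed lists of pathway, process, cell type and brain region genes, 45 had at least 5 members tested. They were tested with camera at a preset correlation of 0.01 between members, and again with the correlation estimated from the data and with fry. Within each list, members were also adjusted over the list alone. A gene was called reversed when it was called in Mod against Con and in 6-OHG against Mod with opposite signs. Because these share the Mod libraries, the count was set beside 100 simulated data sets, independent overlap and splits of the shared libraries.

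Genes named in the text follow a rule. They are the 12 largest rises and 12 largest falls of each comparison among called genes whose groups do not overlap, without predicted or unnamed loci, up to 4 members of each list with the smallest p, all called members of the PI3K/AKT core, and 10 reversed genes. The text gives a selection of these. Genes outside the rule are marked as chosen after their values were seen.

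The procedure was tested on simulated data with 200 changed genes, 50 at each size. At a log2 change of 0.5 it recovered 62%, 64% and 72% of the genes in the 3 comparisons, at -0.5 74%, 76% and 68%, at 1 96%, 92% and 98%, and at 2 100% in each. It called 8, 10 and 12 unchanged genes. The 1 shifted list was found in each comparison, and 0 other lists were called. Genes were simulated independently of each other, so false list calls from correlated members were not tested.

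The other settings tried were a smaller pseudocount, no filter, a filter at 5 FPKM, 3 other scalings, robust moderation, sample weights, fits with only the compared groups, the replicate number as a block, each library left out in turn, a minimum change of 1 and the other list tests. Further settings, added after the data were seen, removed the trend of each library with exon length and GC content, alone and with the replicate block, added a component of the residuals or of the cell type and region lists to the model, or left out the 2 libraries least like their groups. The 2 libraries least like their groups were Con replicate 4 and 6-OHG replicate 2. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.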

Results

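Messenger RNA of mouse brain was measured by sequencing in 13 libraries from male Balb/c mice of 6 to 8 weeks. The labels do not name the brain region. The normal condition (Con) gave 4 libraries, an altitude of 8000 m for 24 h gave 5 (Mod), and the same exposure with 6-OHG gave 4. 6-OHG is a compound that the labels give only by this code, with no dose. The deposited values are FPKM for 37636 genes, of which 13905 reached a mean of 1 over all libraries and were tested. Totals of reads are not given, so the counting error behind a value is unknown. A rough measure, resting on 2.65% to 3.38% of the low values of genes with a single transcript, placed the deepest library at 1.12 times the shallowest. The FPKM columns summed to between 268208 and 312908, and genes encoded in mitochondria took 20.6% to 28.7% of that sum. Across genes, which are not independent replicates, the log2 values of libraries correlated at r = 0.957 to 0.989 within groups and 0.932 to 0.981 between groups. Nothing in the labels says that replicates are separate animals. If they are not, the p-values measure only the spread between these samples, which may be technical.

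Changes below are differences between group means of log2(FPKM + 1), a scale that understates the fold of genes with low values, and levels are mean FPKM ± SD with n = 4 for Con, 5 for Mod and 4 for 6-OHG. A gene or list rose, fell or changed when its adjusted p was under 0.05 in limma. Lists were tested with limma's camera, which compares a list with all other genes and presets the correlation between its members at 0.01.

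The first comparison, Mod against Con, asked what exposure to altitude changed. Ctla2a, which encodes a cysteine protease inhibitor, rose from 1.77 ± 0.375 to 30.9 ± 2.62 FPKM (log2 change 3.53, SE 0.15, adjusted p = 3.71e-08). Angpt2, an antagonist of the endothelial receptor Tek, rose from 0.479 ± 0.165 to 10.1 ± 1.83 FPKM (log2 change 2.90). Vegfa, the main growth factor for vessels, rose 3.28 times, from 20.5 ± 2.04 to 67.0 ± 4.12 FPKM (log2 change 1.67, SE 0.08, adjusted p = 3.71e-08). For each of these genes every Mod library lay above every Con library. The files identify these genes as ENSMUSG00000044258 (Ctla2a), ENSMUSG00000031465 (Angpt2) and ENSMUSG00000023951 (Vegfa). On GRCm38 they lie on chromosome 13 from 60934155 to 60936625, on chromosome 8 from 18690263 to 18741562 and on chromosome 17 from 46016993 to 46032369, each annotated as a protein-coding gene.

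Targets of HIF-1, the transcription factor that low oxygen stabilises, rose as a group. Of 33 members tested 24 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 change of 0.52 and an adjusted p of 3.06e-16. Bnip3, a receptor for the removal of mitochondria, rose from 41.8 ± 1.53 to 107 ± 2.3 FPKM (log2 change 1.33). Egln1, the oxygen sensor that marks HIF for degradation, rose by 0.66 and the transferrin receptor gene Tfrc by 0.74. Glycolysis genes followed, with 11 of 16 higher and 0 lower (12 and 0 adjusted over the list alone, adjusted p = 3.11e-08). Their adjusted p = 0.273 with an estimated correlation. Ldha, which makes lactate dehydrogenase A, rose from 68.4 ± 10.8 to 132 ± 7.43 FPKM, and Gpi1 from 87.9 ± 2.63 to 151 ± 10.1 FPKM.

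**Figure D1:**
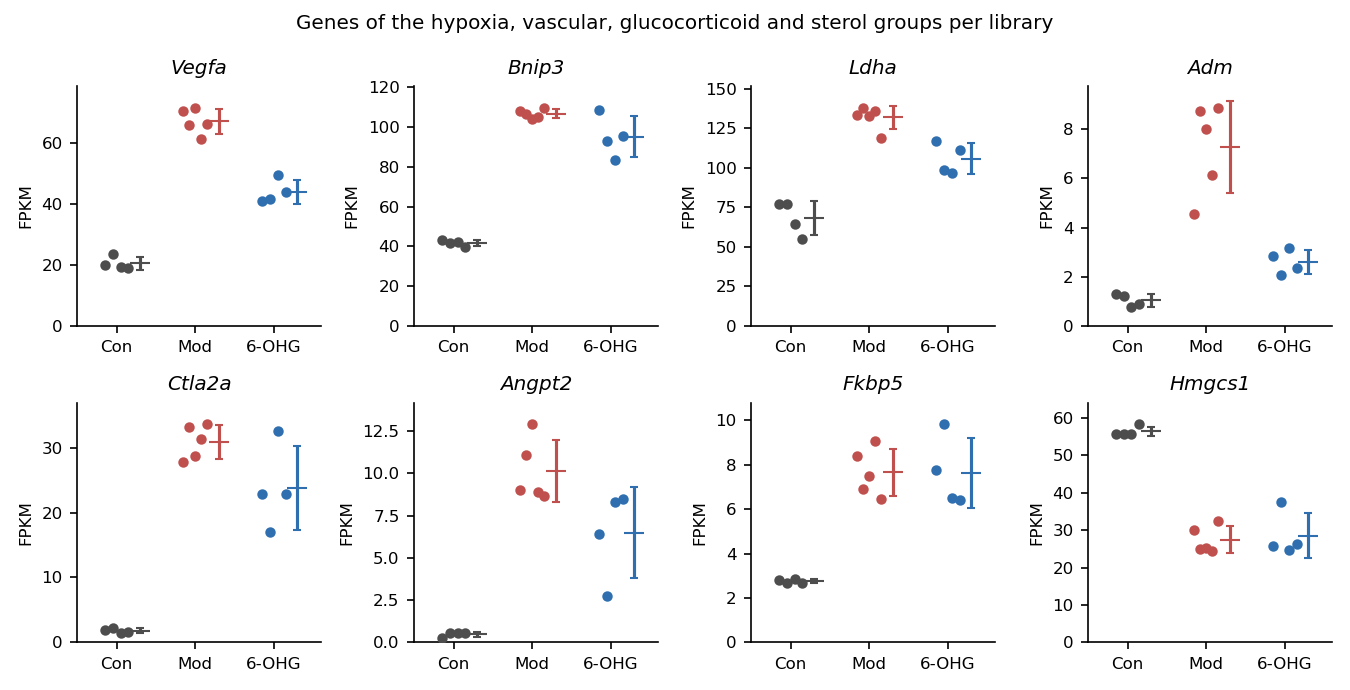
FPKM of 8 genes in each library of Con, Mod and 6-OHG, with the group mean and SD beside the points. Vegfa had means of 20.5, 67.0 and 43.8 FPKM, and Ctla2a of 1.77, 30.9 and 23.8 FPKM.

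Genes that glucocorticoids induce rose in 15 of 23 cases and fell in 0 (18 and 0 adjusted over the list alone). The median change was 0.70, with an adjusted p of 3.01e-09, and adjusted p = 0.273 with an estimated correlation. Fkbp5, a regulator of the glucocorticoid receptor, rose from 2.77 ± 0.0855 to 7.66 ± 1.07 FPKM, and Plin4, a lipid droplet protein, from 0.450 ± 0.187 to 9.14 ± 2.1 FPKM. Hif3a rose by 1.75 on the log2 scale. Members of the apoptosis list changed both ways, with 8 of 21 higher and 2 lower (8 and 2 adjusted over the list alone, adjusted p = 0.0297, adjusted p = 0.273 with an estimated correlation). The proapoptotic Pmaip1 rose by 0.55, Casp8 by 0.61 and Trp53 by 0.35, while Bcl2, which protects cells from apoptosis, fell by 0.44. Without genes under a mean of 5 FPKM the apoptosis list was not called (adjusted p = 0.286). Circadian clock genes were higher in 8 of 18 cases and lower in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.0471, adjusted p = 0.671 with an estimated correlation). Per3 rose by 0.59 and Ciart by 0.84. That call ended without Con replicate 4 (median 0.17, adjusted p = 0.166), without Mod replicate 4 (0.0691) and without 6-OHG replicate 3 (0.0512), with sample weights (0.0839) and without the 2 libraries least like their groups (0.151).

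Cholesterol synthesis and uptake fell as a group: of 24 members 18 fell and 1 rose (20 and 1 adjusted over the list alone). The median was -0.53 and the adjusted p 5.39e-11, with adjusted p = 0.354 with an estimated correlation. Hmgcs1, an early enzyme of the pathway, fell from 56.4 ± 1.28 to 27.4 ± 3.62 FPKM (log2 change -1.02), and Srebf2, the transcription factor that drives it, from 25.3 ± 1.82 to 14.2 ± 0.654 FPKM. Of the heat shock proteins 9 of 21 fell and 0 rose (11 and 0 adjusted over the list alone, adjusted p = 3.71e-05, adjusted p = 0.273 with an estimated correlation). Cryab fell from 54.0 ± 4.54 to 27.1 ± 3.92 FPKM and Hsph1 fell by 0.87 on the log2 scale. Ribosomal protein genes were higher in 7 of 40 cases and lower in 0 (6 and 0 adjusted over the list alone, median 0.15, adjusted p = 0.00172, adjusted p = 0.771 with an estimated correlation), Rpl3 by 0.35. That median was 0.08 with FPKM rescaled to equal sums (adjusted p = 0.0140) and 0.09 after removal of the trend of each library with exon length and GC content (adjusted p = 0.0321).

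Synaptic lists fell by less. In the synaptic plasticity and memory list 6 of 37 fell and 0 rose (4 and 0 adjusted over the list alone, median -0.11, adjusted p = 0.0143, adjusted p = 0.771 with an estimated correlation). Bdnf, a neuronal growth factor, fell from 2.83 ± 0.724 to 1.30 ± 0.447 FPKM, and its receptor gene Ntrk2 fell by 0.28. The lowest means of the plasticity list in the 3 groups were those of Con replicate 4, Mod replicate 5 and 6-OHG replicate 2. The same libraries had the lowest means of the striatum markers in their groups (3.68, 2.55 and 2.13 on the log2 scale). Whether the tissue taken differed between libraries was not tested. In the presynaptic vesicle list 4 of 24 fell and 0 rose (4 and 0 adjusted over the list alone, adjusted p = 0.037, adjusted p = 0.663 with an estimated correlation), among them Unc13a (-0.73) and Syt4 (-0.28). The plasticity call ended in 4 of 28 settings, without Con replicate 2 (adjusted p = 0.0522), without genes under 5 FPKM (0.0612), and after removal of the trend with exon length and GC content (0.0720) or of that trend with the replicate block (0.146), and its median was -0.07 without Con replicate 1 and -0.22 without Con replicate 4. The presynaptic call ended in 6, without Con replicate 3 (0.0754), without Mod replicate 3 (0.0739), without genes under 5 FPKM (0.0612), after quantile normalization (0.0545), and after removal of the trend alone (0.0708) or with the block (0.0900).

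Markers of several cell types moved with these groups. Microglia markers fell in 4 of 17 cases and rose in 0 (4 and 0 adjusted over the list alone, adjusted p = 0.00533, adjusted p = 0.671 with an estimated correlation), including Tmem119 (-0.46) and Sall1 (-0.40). Oligodendrocyte precursor markers fell in 3 of 11 cases and rose in 0 (3 and 0 adjusted over the list alone, adjusted p = 0.0116, adjusted p = 0.663 with an estimated correlation), Olig2 by -0.80. Both calls ended without genes under 5 FPKM (adjusted p = 0.395 and 0.0661). Oligodendrocyte and myelin markers fell in 3 of 15 cases and rose in 0 (3 and 0 adjusted over the list alone, adjusted p = 0.0406, adjusted p = 0.811 with an estimated correlation). Ugt8a, which makes a myelin lipid, fell from 32.8 ± 4.25 to 10.6 ± 2.18 FPKM. That call ended in 8 of 28 settings. These were the fits without Con replicate 4 (median -0.19, adjusted p = 0.144), without Mod replicate 4 (-0.16, 0.190) and without the 2 libraries least like their groups (0.151), the 5 FPKM filter (0.0687), median-of-ratios scaling (0.0605), quantile normalization (0.0762), sample weights (0.123) and removal of the length and GC trend (0.0558). Hypothalamus markers were higher in 4 of 10 cases and lower in 0 (4 and 0 adjusted over the list alone, median 0.83, mean 0.94), and the list was not called (adjusted p = 0.201). Endothelial markers changed both ways, with 6 of 14 higher and 4 lower (7 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.838, median 0.17, mean -0.07). Pecam1 rose by 0.85, Esam by 1.03 and Cdh5 by 0.81, while Itm2a fell by 1.98, from 30.6 ± 2.55 to 7.07 ± 1.23 FPKM, and the transporter gene Slco1a4 fell by 1.26.

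Among the 12 largest falls were 3 genes of liver secretion and lipid handling, Apoa2 (-2.38), Fabp1 (-1.93) and Apoa1 (-1.83). A set of 32 liver transcripts summed to 86.4 to 118 FPKM in the Con libraries, 100.5 in Mod replicate 3, and 15.9 to 19.3 in the other 4 Mod libraries. Some of its members had already been seen to differ in these data. The 21 members not seen before summed to 38.1 to 42.9 FPKM in Con and 39.7 in Mod replicate 3. In the other 4 Mod libraries they summed to 15.1 to 19.0.

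The PI3K/AKT core, the pathway that the series names for cognitive dysfunction at altitude, changed both ways and was not called (median -0.02, mean -0.03, adjusted p = 0.231). Of 41 members 4 rose and 7 fell (4 and 8 adjusted over the list alone). Akt2, a main kinase of the pathway, fell from 11.0 ± 3.17 to 6.36 ± 0.831 FPKM (log2 change -0.67, SE 0.18) and the upstream kinase gene Pdpk1 fell by 0.32. Pik3r3, a regulatory subunit of PI3K, fell by 0.31, Bcl2 by 0.44 and the AKT phosphatase gene Phlpp1 by 0.29. Tsc1, an inhibitor of mTOR complex 1, rose from 7.16 ± 0.419 to 9.91 ± 0.433 FPKM, Inpp5d rose by 0.36, Sgk3 by 0.43 and Rictor by 0.17. Akt2 lost its call without Con replicate 1 (adjusted p = 0.0543) or 2 (0.0530). Rictor and Sgk3 each lost theirs in 7 of 13 fits that left out 1 library, with adjusted p up to 0.114 (without Con replicate 1) and 0.0751 (without Con replicate 3). Akt2, ENSMUSG00000004056, lies on chromosome 7 from 27591552 to 27640826, and Bcl2, ENSMUSG00000057329, on chromosome 1 from 106538178 to 106714274.

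**Figure D2:**
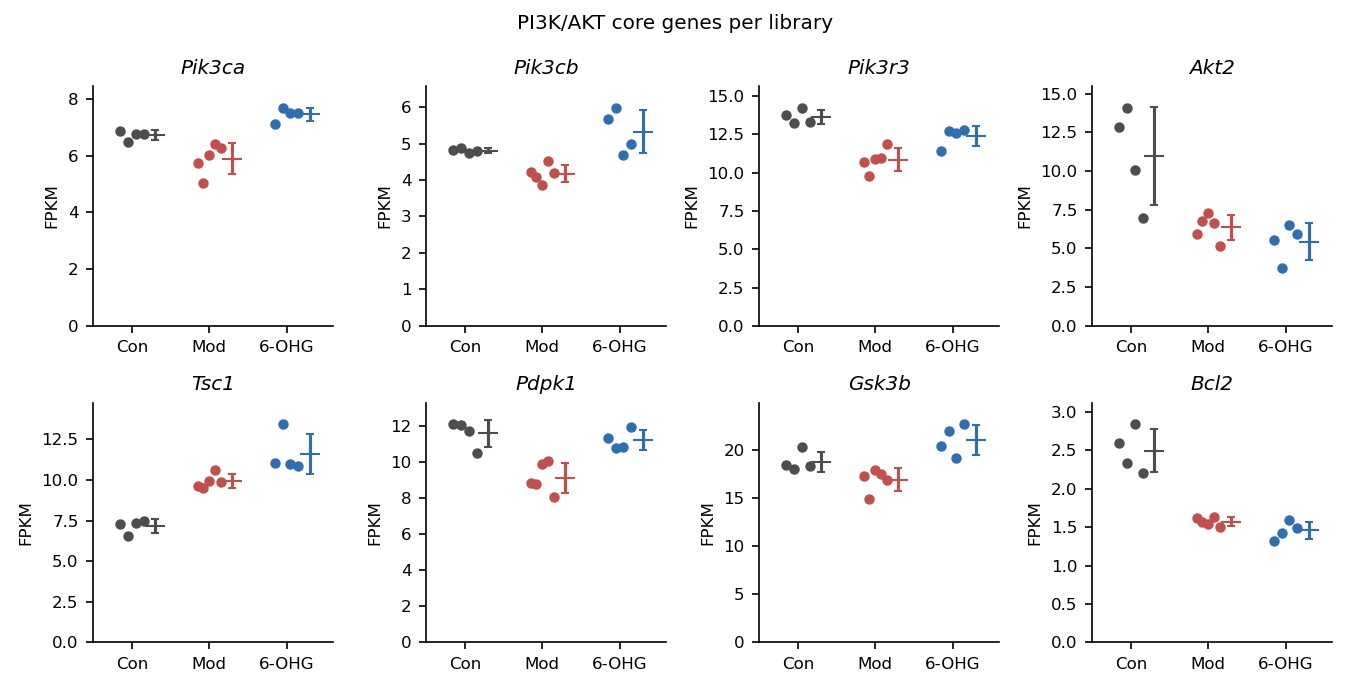
FPKM of 8 members of the PI3K/AKT core in each library, with the group mean and SD beside the points. Akt2 had means of 11.0, 6.36 and 5.44 FPKM in Con, Mod and 6-OHG, and Pik3ca of 6.71, 5.89 and 7.45 FPKM.

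In total 3304 genes changed between Mod and Con, 1940 higher and 1364 lower, with a median size of 0.35 among them. A change of at least 1 was seen in 91 of the higher and 29 of the lower genes. The groups did not overlap for 3108 genes, which is 22.4% of those tested, against 1.59% by chance. With FPKM rescaled to equal sums, 41.2% of the called genes were higher, against 58.7% as deposited. Of the 13 lists called, the HIF-1 targets alone kept the call with an estimated correlation (adjusted p = 7.76e-05). The directional test of limma's fry, which asks whether the genes of a list move one way on balance, called 14 lists, and its mixed test, which asks for changes in either direction, called 31. Neither compares a list with other genes.

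The second comparison, 6-OHG against Mod, asked what 6-OHG changed in exposed mice. Part of the hypoxia response was lower with 6-OHG. Vegfa stood at 43.8 ± 3.9 FPKM, against 67.0 ± 4.12 in Mod (log2 change -0.60, SE 0.08, adjusted p = 0.00113). Adm, a peptide that widens vessels, was at 2.61 ± 0.496 against 7.27 ± 1.86 FPKM (-1.17), and the vascular growth factor gene Pgf at 0.892 ± 0.274 against 2.72 ± 0.768 FPKM (-0.96). Slc16a3, a lactate exporter, fell by 0.48. For these 4 genes all 6-OHG libraries lay below all Mod libraries. Of the HIF-1 targets 8 of 33 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.12, adjusted p = 0.00441, adjusted p = 0.123 with an estimated correlation). Glycolysis genes fell in 8 of 16 cases and rose in 0 (8 and 1 adjusted over the list alone, adjusted p = 0.00184, adjusted p = 0.685 with an estimated correlation). Pfkl fell by 0.42 and Tpi1, from 258 ± 7.73 to 211 ± 13.9 FPKM, by 0.29. The HIF-1 median was -0.02 with FPKM rescaled to equal sums (adjusted p = 0.00389) and -0.08 after quantile normalization (0.0119), and the call ended without genes under 5 FPKM (0.313). The glycolysis median of -0.21 became -0.11 with rescaling (0.00959) and -0.12 after removal of the trend with length and GC content (0.00763), and its call ended after quantile normalization (median -0.07, adjusted p = 0.208).

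Ribosomal protein genes and genes of oxidative phosphorylation were the groups with the lowest p. Of 40 ribosomal protein genes 35 fell and 0 rose (37 and 0 adjusted over the list alone, median -0.40, adjusted p = 2.52e-20, adjusted p = 0.542 with an estimated correlation). Rps21 (ENSMUSG00000039001, chromosome 2 from 180257377 to 180258445) fell from 70.5 ± 4.18 to 43.5 ± 4.93 FPKM. Many ribosomal protein genes have processed copies elsewhere in the genome, and how shared reads were assigned is not stated. Of 40 nuclear genes of oxidative phosphorylation 25 fell and 0 rose (33 and 0 adjusted over the list alone, median -0.30, adjusted p = 1.12e-12, adjusted p = 0.542 with an estimated correlation), such as Ndufa2, a subunit of complex I, from 41.8 ± 4.26 to 23.7 ± 2.79 FPKM. Both groups have short transcripts. Changes between 6-OHG and Mod followed the summed exon length of genes across the 13894 genes with a known length (r = 0.36, rho 0.46). Among genes over 4 kb 844 rose and 178 fell, and among genes of 1 to 2 kb 25 rose and 352 fell. After the trend of each library with exon length and GC content was removed, 22 of the 35 ribosomal and 12 of the 25 oxidative phosphorylation genes were still called lower.

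**Figure D3:**
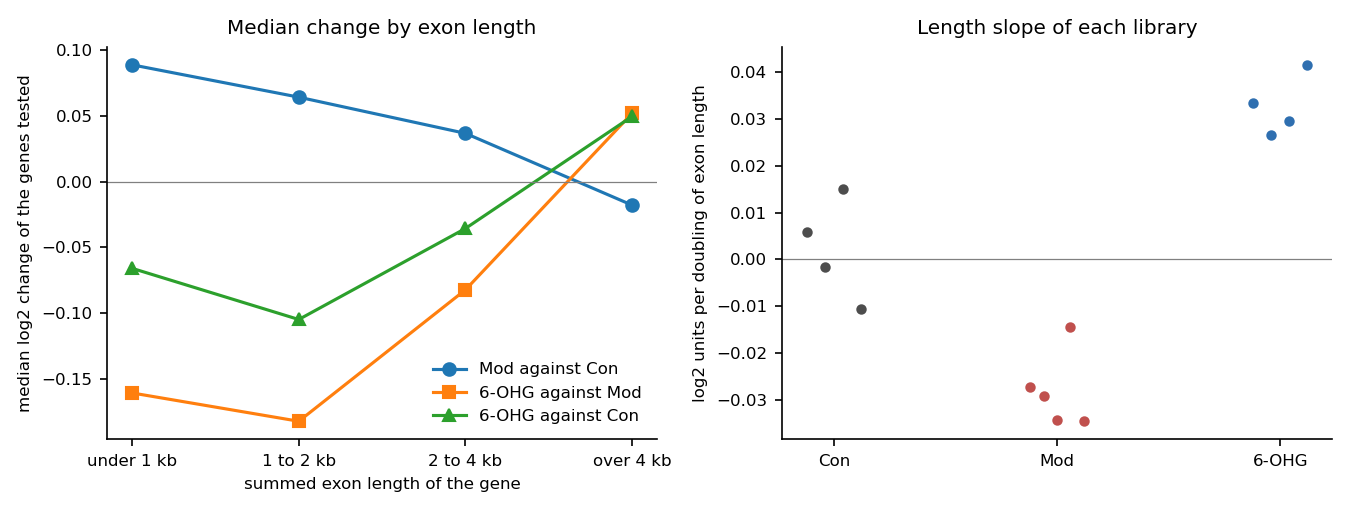
Left, median log2 change of tested genes by summed exon length in the 3 comparisons; right, slope of each library on log2 exon length after subtraction of gene means. In 6-OHG against Mod the medians ran from -0.16 under 1 kb and -0.18 at 1 to 2 kb to 0.05 over 4 kb, and the slopes were below 0 in all 5 Mod libraries and above 0 in all 4 6-OHG libraries.

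PI3K/AKT core genes were slightly higher with 6-OHG as a group. Of 41 members 9 rose and 2 fell (16 and 2 adjusted over the list alone, median 0.09, adjusted p = 0.0138, adjusted p = 0.542 with an estimated correlation). Pik3ca, the catalytic subunit alpha of PI3K (ENSMUSG00000027665, chromosome 3 from 32397671 to 32468486), rose from 5.89 ± 0.545 to 7.45 ± 0.238 FPKM (log2 change 0.30, SE 0.06), and Pik3cb from 4.18 ± 0.239 to 5.33 ± 0.599 FPKM. Gsk3b, a kinase that AKT inhibits, rose by 0.30, Rictor by 0.26, Pdpk1 by 0.27, Irs2 by 0.39, Pkn2 by 0.25, Phlpp2 by 0.26 and Rptor by 0.18, while Bad fell by 0.33. Core members have a median exon length of 7602 bases, against 4102.5 for all genes tested. After the trend with length and GC content was removed, 1 of the 9 higher members, Irs2, was still called and the list was not (adjusted p = 0.27, and 0.281 with the replicate block). Pdpk1 lost its call without 6-OHG replicate 4 (adjusted p = 0.0575), and Rptor and Phlpp2 lost theirs in 10 and 7 of 13 fits that left out 1 library (adjusted p up to 0.0865 and 0.0863). The list's median was 0.05 without Mod replicate 2 and 0.20 with FPKM rescaled to equal sums.

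Lists of immediate early and synaptic genes were higher with 6-OHG. Kcna1, a potassium channel gene, rose 1.98 times, from 9.42 ± 1.2 to 18.7 ± 1.33 FPKM, and Gabrb2, a subunit of the GABA-A receptor, rose from 9.98 ± 1.07 to 19.6 ± 1.8 FPKM. Immediate early genes, which neuronal activity switches on, rose in 7 of 23 cases and fell in 0 (10 and 0 adjusted over the list alone, median 0.55, adjusted p = 1.42e-05, adjusted p = 0.743 with an estimated correlation). The median was 0.31 with the first component of the cell type and region lists as a term (adjusted p = 0.000353), and the mean of the list in 6-OHG replicate 2 lay below those in Mod replicates 1 and 3. Fosl2 rose by 0.57, and Fos by 1.04, from 6.05 ± 3.14 to 12.7 ± 3.00 FPKM. The call of Fos ended without Mod replicate 2 (adjusted p = 0.0537) or 6-OHG replicate 1 (0.0517), 3 (0.0670) or 4 (0.0625). Presynaptic vesicle genes rose in 4 of 24 cases and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.0198, adjusted p = 0.685 with an estimated correlation), Pclo by 0.48. That call ended without Mod replicate 3 (adjusted p = 0.0594) or 6-OHG replicate 1 (0.0906), and after removal of the length trend with the replicate block (0.0642). The plasticity list rose with 2 of 37 members higher (0 adjusted over the list alone, adjusted p = 0.0136, adjusted p = 0.885 with an estimated correlation), with a median of 0.13 overall and 0.23 without 6-OHG replicate 2. Its call ended without 6-OHG replicate 1 (adjusted p = 0.0860). It also ended after removal of the length trend alone (median 0.06, adjusted p = 0.200) or with the replicate block (0.05, 0.347). With the first component of the cell type and region lists as a term it ended too (median 0.08, adjusted p = 0.10). Circadian clock genes rose in 2 of 18 cases and fell in 1 (2 and 1 adjusted over the list alone, adjusted p = 0.0271, adjusted p = 0.821 with an estimated correlation), Per1 by 0.43, a call that ended without 6-OHG replicate 1 (median 0.05, adjusted p = 0.209) or 3 (0.0668), with the cell type and region component (0.108), and after removal of the length trend with the block (0.0573).

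Among markers of cell types and regions, 3 lists were lower in 6-OHG than in Mod. Region markers also varied within groups. The mean log2 value of the striatum markers ran from 2.55 to 4.58 in Mod and from 2.13 to 4.27 in 6-OHG. Whether dissection differed between libraries was not tested. Hypothalamus markers fell in 4 of 10 cases and rose in 0 (8 and 0 adjusted over the list alone, median -1.11, adjusted p = 0.00238, adjusted p = 0.685 with an estimated correlation). Without a filter on FPKM the median was -0.55 (adjusted p = 1.17e-05). These markers stood higher in Mod than in Con (median 0.83, not called), and in 6-OHG against Con the median was -0.42 with the list not called (adjusted p = 0.210). Hcrt, the orexin precursor, fell from 7.60 ± 2.51 to 0.891 ± 1.04 FPKM, against 2.06 ± 2.38 FPKM in Con. Ependyma markers fell in 2 of 6 cases and rose in 0 (3 and 0 adjusted over the list alone, adjusted p = 0.0260, adjusted p = 0.685 with an estimated correlation), a call that ended in 7 of 27 settings with adjusted p up to 0.133. Among these were the fits without Mod replicate 3 (adjusted p = 0.0514), without 6-OHG replicate 1 (0.0720), after removal of the length trend (0.0864) and with the cell type and region component (0.0610). Oligodendrocyte and myelin markers fell as a list with 0 of 15 members called (0 adjusted over the list alone, median -0.33, adjusted p = 0.0330, adjusted p = 0.994 with an estimated correlation). That call ended in 12 of 28 settings, among them the fits without Mod replicate 2 (0.0709), 3 (0.0698) or 5 (0.195) and without 6-OHG replicate 1 (median -0.15, 0.394) or 2 (0.134). It also ended with the 5 FPKM filter (0.114), quantile normalization (0.0694), sample weights (0.0923), the replicate block (0.165) and the cell type and region component (0.120).

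In total 2131 genes changed between 6-OHG and Mod, 970 higher and 1161 lower, with a median size of 0.32. A change of at least 1 was seen in 8 and 13 of them. The groups did not overlap for 2216 genes, 15.9% against 1.59% by chance. The share of higher genes was 45.5% as deposited, 77.6% with FPKM rescaled to equal sums and 57.5% after quantile normalization. Without 6-OHG replicate 4 the count was 1357 and with the replicate number as a block 846. After removal of the length and GC trend it was 992, and 782 of the 2131 genes, 36.7%, were still called in the same direction. With the trend removed and the block together the count was 74. Of the 12 lists called 0 kept the call with an estimated correlation, and all 12 had a median that some other setting moved by over 1.5 times, against 7 of 13 in Mod against Con and 4 of 12 in 6-OHG against Con. The directional test of fry called 8 lists and its mixed test 19.

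Part of the altitude response moved the other way with 6-OHG. Of the genes changed between Mod and Con, 527 changed the opposite way between 6-OHG and Mod, 280 from a rise to a fall and 247 from a fall to a rise. Another 132 moved further from Con. Independent calls would have given 162 and 95.2 opposite pairs. Vegfa, Adm and Fam162a, a target of HIF-1, rose and then fell, and Herc2, a ubiquitin ligase gene, fell and then rose. The comparisons share the Mod libraries, so opposite signs arise without any effect of 6-OHG. In 100 simulations with 6-OHG equal to Mod the mean count was 3.68, with up to 367. In 20 splits of the Mod libraries into separate sets the reversed count had a median of 1.5 and a range of 0 to 61, but these fits hold 2 or 3 Mod libraries per comparison and called 618 to 2162 altitude genes, so their counts cannot be set against 527. Opposite signs were seen in 64.1% of the altitude genes, within the range of the simulations (38.0% to 80.5%), so that share shows no excess over what sharing Mod gives. In the splits, where no library is shared, the share was 51.5% to 66.5% with a median of 57.7%, and changes of the 2 comparisons correlated across genes at a median r of -0.09 (-0.21 to 0.04), below 0 in 19 of 20 splits. The splits overlap, and simulations with 6-OHG equal to Mod, run after the split values were seen, gave a median share as high in 17 of 100 and a median r as low in 20 of 100, so neither is beyond what these simulations give. The 6-OHG mean lay nearer to Con than to Mod for 26.5% of the altitude genes, a share without a test per gene. In the simulations the mean share was 5.06% and the highest 23.6%. The simulations hold no trend with exon length that separates 6-OHG from Mod. Changes followed log2 exon length at r = -0.14 in Mod against Con and 0.36 in 6-OHG against Mod. Opposite trends also give opposite changes, so neither the 26.5% nor the 527 separates an effect of 6-OHG from them. The count of 527 fell to 347 without Mod replicate 2, 343 without Mod replicate 3 and 317 without 6-OHG replicate 4. It fell to 271 after removal of the length and GC trend, to 181 with the replicate block and to 25 with both.

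The third comparison, 6-OHG against Con, asked what differed from normal after exposure with 6-OHG. Of the 6 lists that were higher in Mod, 4 were also higher here. HIF-1 targets were higher in 22 of 33 cases and lower in 1, Ndrg1 (25 and 1 adjusted over the list alone, median 0.52, adjusted p = 3.28e-09, adjusted p = 0.000941 with an estimated correlation). Ndrg1 was named after its values were seen. Bnip3 stood at 95.1 ± 10.4 FPKM against 41.8 ± 1.53 in Con, Vegfa at 2.14 times its Con level, and Ctla2a at 23.8 ± 6.46 FPKM against 1.77 ± 0.375. Glucocorticoid-induced genes rose in 16 of 23 cases and fell in 0 (19 and 0 adjusted over the list alone, adjusted p = 4.5e-09, adjusted p = 0.464 with an estimated correlation), with Fkbp5 at 7.63 ± 1.58 FPKM. Glycolysis genes rose in 9 of 16 cases and fell in 0 (10 and 0 adjusted over the list alone, adjusted p = 0.00232, adjusted p = 0.470 with an estimated correlation), Gpi1 by 0.51. Circadian clock genes rose in 9 of 18 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.00129, adjusted p = 0.464 with an estimated correlation), Per3 by 0.71.

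Lower lists were again led by cholesterol synthesis and uptake, with 17 of 24 lower and 1 higher (19 and 1 adjusted over the list alone, median -0.63, adjusted p = 7.02e-09, adjusted p = 0.464 with an estimated correlation). Srebf2 stood at 14.2 ± 0.605 FPKM. Heat shock proteins fell in 11 of 21 cases and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.000207, adjusted p = 0.464 with an estimated correlation). Cryab fell by 1.38, and the list's median of -0.21 became -0.34 without Con replicate 2 and -0.39 without 6-OHG replicate 2. Oxidative phosphorylation genes fell in 23 of 40 cases and rose in 0 (26 and 0 adjusted over the list alone, adjusted p = 2.92e-08, adjusted p = 0.464 with an estimated correlation), Atp5d by 0.60. Ribosomal protein genes also fell in 23 of 40 cases and rose in 0 (26 and 0 adjusted over the list alone, adjusted p = 2.21e-07, adjusted p = 0.470 with an estimated correlation), Rps9 by 0.52. After quantile normalization the median of the oxidative phosphorylation genes went from -0.26 to -0.14 (adjusted p = 0.000562) and that of the ribosomal protein genes from -0.27 to -0.16 (0.00125), and the ribosomal median was -0.17 after removal of the length and GC trend (0.000127). The correlation of the changes with exon length was 0.13 here (rho 0.19).

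**Figure D4:**
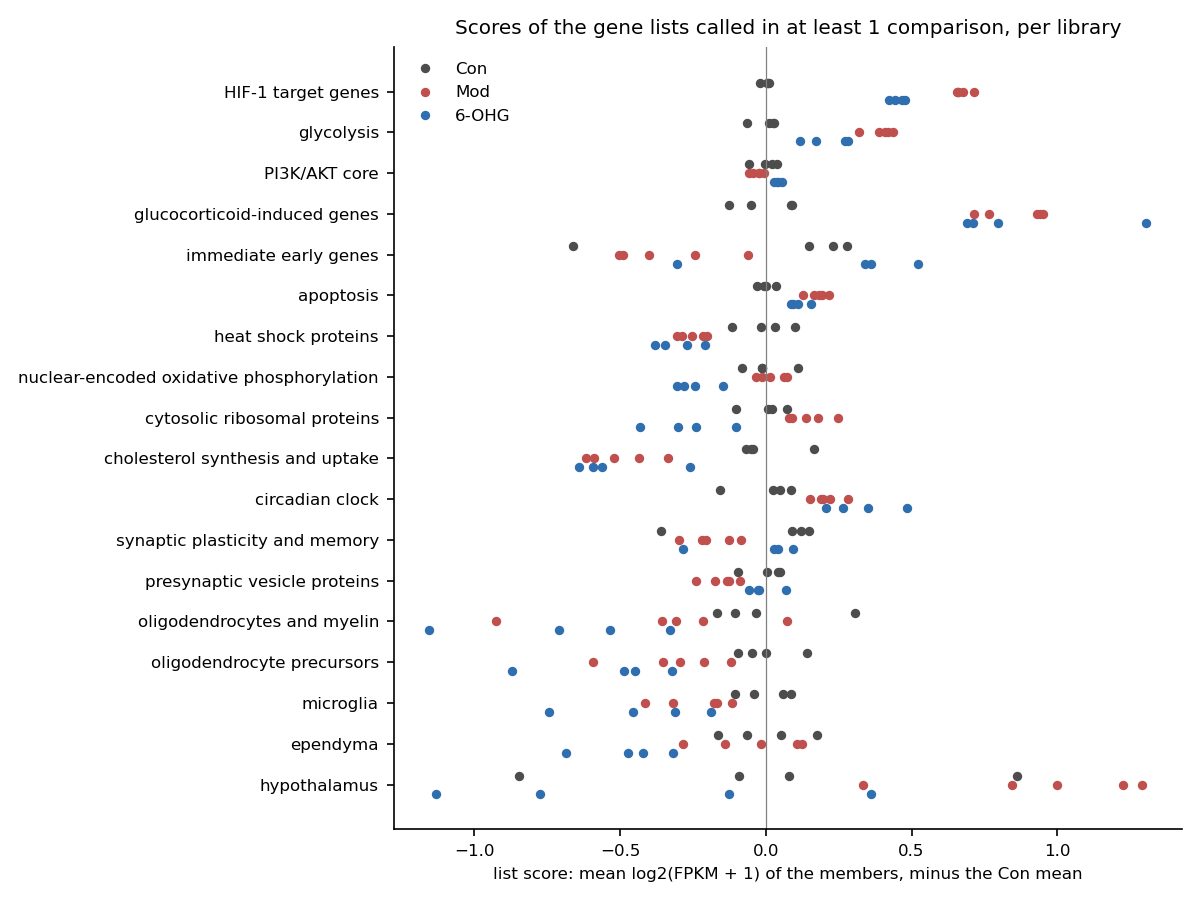
Mean log2(FPKM + 1) of the members of each list called in at least 1 comparison, per library and minus the Con mean. HIF-1 targets were above Con in all 9 exposed libraries, and ribosomal protein genes lay below the Con mean in all 4 6-OHG libraries.

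Of the cell type lists, 4 were called lower than in Con, while markers such as those of endothelium (6 higher and 5 lower of 14) and astrocytes (2 and 2 of 15) were not. Microglia markers fell in 10 of 17 cases and rose in 0 (13 and 0 adjusted over the list alone, adjusted p = 4.83e-05, adjusted p = 0.470 with an estimated correlation), Tmem119 by 0.71, and the call ended without genes under 5 FPKM (adjusted p = 0.0727). Oligodendrocyte precursor markers fell in 6 of 11 cases and rose in 0 (6 and 0 adjusted over the list alone, adjusted p = 0.00209, adjusted p = 0.470 with an estimated correlation), Olig2 from 13.0 ± 1.67 to 4.82 ± 1.39 FPKM. Oligodendrocyte and myelin markers fell in 6 of 15 cases and rose in 0 (8 and 0 adjusted over the list alone, adjusted p = 0.000454, adjusted p = 0.641 with an estimated correlation). Ugt8a was at 8.75 ± 3.73 FPKM. Ependyma markers fell in 3 of 6 cases and rose in 0 (3 and 0 adjusted over the list alone, adjusted p = 0.0307, adjusted p = 0.464 with an estimated correlation), a call that ended in 7 of 27 settings with adjusted p up to 0.0658. Among these were the fits without Con replicate 2 (adjusted p = 0.0546) or 4 (0.0542), after removal of the length trend (0.0577) and with the cell type and region component (0.0565). Fabp7, a lipid carrier of glial progenitors, fell from 25.9 ± 1.31 to 5.25 ± 0.728 FPKM.

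The largest fall was that of Alb, the gene of serum albumin (ENSMUSG00000029368, chromosome 5 from 90460897 to 90476602), from 17.4 ± 2.09 to 0.0812 ± 0.0424 FPKM. Nppa, a hormone gene of the heart, fell from 16.0 ± 5.25 to 0.393 ± 0.426 FPKM. Mup7, Fabp1 and Serpina3k were listed at 0 in all 4 6-OHG libraries. Reads of the Mup and Serpina families are hard to assign to a single member. The 32 liver transcripts summed to 13.2 to 23.0 FPKM in the 6-OHG libraries, against 86.4 to 118 in Con, and 18 transcripts of heart and muscle to 12.5 to 19.1 FPKM, against 33.5 to 83.0. Both sets hold members already seen in these data. The 21 liver members not seen before summed to 12.2 to 22.7 FPKM in 6-OHG, against 38.1 to 42.9 in Con. For the 14 such members of heart and muscle the sums were 10.4 to 18.0 FPKM, against 17.3 to 45.2, so these ranges overlap.

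The PI3K/AKT core was not called against Con (adjusted p = 0.602, median 0.04), although 10 of 41 members rose and 6 fell (11 and 7 adjusted over the list alone). Tsc1 rose by 0.62, Sgk3 by 0.50, Rictor by 0.44, Pik3r1 by 0.33, Irs2 by 0.32, Rps6kb1 by 0.31 and Pkn2 by 0.29. Akt2 fell from 11.0 ± 3.17 to 5.44 ± 1.19 FPKM, Bcl2 fell by 0.50, Phlpp1 by 0.29 and Rheb by 0.25. Creb1 (0.25), Cdkn1b (0.22) and Them4 (-0.30) were also called, and lost the call in 5, 5 and 9 of 13 fits that left out 1 library, with adjusted p up to 0.0848 (without 6-OHG replicate 1), 0.0747 and 0.119 (both without 6-OHG replicate 3). Irs2 lost its call without Con replicate 2 (0.0545).

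In total 4268 genes changed between 6-OHG and Con, 2270 higher and 1998 lower, with a median size of 0.38. A change of at least 1 was seen in 74 and 57 of them. The groups did not overlap for 3913 genes, 28.1% against 2.86% by chance. Of the 12 lists called 1 kept the call with an estimated correlation, the HIF-1 targets, and fry's directional test called 19 and its mixed test 32. In both exposed groups 2053 genes changed the same way against Con, 1227 higher and 826 lower, against 317 and 196 for independent calls, and 21 changed in opposite ways. Changes against Con in the exposed groups correlated across genes at r = 0.74, but both hold the Con libraries, and simulations with no effect gave a mean of 0.50 with 95% of them between -0.02 and 0.84, so this r is not beyond what sharing Con gives. Their covariance was 0.0723, against a mean of 0.0111 in those simulations, 95% of which lay between -0.000228 and 0.0318. With separate parts of Con in 6 splits, where no library is shared, r had a median of 0.515 (0.458 to 0.657). The covariance and the splits argue against sharing Con as the whole source of the common changes. They do not separate exposure from handling that sets Con apart.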

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

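Of the tests in this part, the ones of exposed libraries that reach Con in liver or heart transcripts and of the PI3K/AKT core after removal of the length trend were chosen only after the result was seen, as were the simulations of HIF-1 targets in other scalings and the removal of the trend and the component of the cell type lists as alternatives.

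A library stood apart from the others of its group in 44 of 444 groups of values tested, where chance gives about 1 in 20 groups, or 22.2. The measure is the gap of the highest or lowest library to its nearest neighbour over the range of the group, with the 95% critical values of Dixon as limits. Con replicate 4 was the library in 12 cases and Mod replicate 3 in 9. The groups of values are not independent, since related genes move together and list scores were tested beside genes of the same lists. All 9 cases of Mod replicate 3 were liver transcripts. The excess of 44 over 22.2 is therefore not a measure of how many libraries are unusual. Con replicate 4 had the highest relative depth of its group (0.965). It was highest for the scores of cholesterol synthesis and uptake (0.897) and for Hmgcs1 (0.931) and Gng11 (0.860), and lowest for the scores of synaptic plasticity and memory (0.890) and immediate early genes (0.861). It was also lowest for Hsph1 (0.832), Fam205c (0.873), Per1 (0.933), Mup3 (0.864), Mup7 (0.897) and Serpina1c (0.897). Mod replicate 3 was highest for Apoa2 (0.937), Fabp1 (0.922), Apoa1 (0.792), Alb (0.935), Mup20 (0.981), Mup3 (0.930), Mup7 (1), Serpina1c (0.872) and Serpina3k (0.953).

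The remaining cases were spread over libraries. In Con they were Angpt2 (0.904), Wnt10b (0.855), Sostdc1 (0.878), Pmaip1 (0.892), Slc16a3 (0.901) and Alb (0.842). In Mod they were Wnt10b (0.732), Ldha (0.755), Rpl3 (0.827) and Gng11 (0.825). In 6-OHG, replicate 1 was lowest for Prelp (0.877), Pik3r3 (0.879), Olig2 (0.836) and Slc16a3 (0.869) and highest for Pkn2 (0.862). Replicate 2 was highest for Tsc1 (0.912), Hmgcs1 (0.849), Rptor (0.871) and Mup20 (1) and lowest for Trp53 (0.843) and Calr (0.857). Replicate 4 was lowest for Slco1a4 (0.917) and replicate 3 highest for Mup3 (1). The values of 1 for Mup genes come from libraries of which all but 1 were listed at 0.

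Liver and heart transcripts were higher in Con than in 6-OHG. Of the liver list members not examined before the test, 20 of 21 (95.2%) were higher in Con, as RNA of liver in the Con libraries would give. Lower expression in every exposed brain is argued against by 3 exposed libraries that reached the lowest Con library, Mod replicate 3 in liver transcripts and Mod replicates 1 and 2 in those of heart and muscle. Carry-over of RNA from other organs is therefore a candidate source, while the step at which it entered was not tested and a biological source in the groups stays open. Reads shared within the Mup family leave its single members uncertain.

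In 6-OHG against Mod 35 of 40 ribosomal protein and 25 of 40 oxidative phosphorylation genes were lower, and 9 of 41 PI3K/AKT core genes higher and 2 lower, along a trend with exon length. None of the 3 list calls held with an estimated correlation (adjusted p = 0.542 each). After the trend of each library with exon length and GC content was removed, the ribosomal median was -0.26 (SD of members 0.17), against -0.40 before. Exon length is summed over all annotated exons of a gene, which can exceed the length of the transcripts expressed. A trend with transcript length may thus be removed only in part, and what is left does not show a cause beyond length. The median after median-of-ratios scaling was -0.38, which argues against a few abundant genes taking a larger share. For oxidative phosphorylation the median went from -0.30 (SD 0.18) to -0.13 (SD 0.15) with 12 of 25 members and the list itself still called (adjusted p = 5.99e-09), and the trend and an effect of 6-OHG cannot be told apart, since the trend differs between the groups. For the PI3K/AKT core 1 of 9 higher members was still called, the median went from 0.09 (SD 0.18) to 0.05 (SD 0.14), and the trend may account for the list's call, although an effect of 6-OHG on long genes would look alike.

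HIF-1 targets were lower in 6-OHG than in Mod. After removal of the length and GC trend 87.5% of the 8 lower members were still called, against 36.7% of all called genes. Larger changes outlast such a removal more easily, and the 8 members were not matched in size to all called genes, so these shares do not decide. With the trend removed camera still called the list (median -0.09, adjusted p = 0.000835). The trend as fitted on summed exon length and GC content thus does not account for the whole call. A trend with the length of the transcripts expressed may be removed only in part here too. With the first component of the cell type and region lists as a term 100% were still called, but so were 99.8% of all 2131 called genes. That test therefore cannot decide on tissue make-up. In 0 of 100 simulations with 6-OHG equal to Mod was the list's median as low as -0.12, the lowest being -0.05, for FPKM as deposited. With FPKM rescaled to equal sums the median was -0.02, and 30 of 100 simulations were as low. Taken relative to the median of all genes, the list lay at -0.10 as deposited and -0.09 with rescaling, and 0 of 100 simulations were as low in either. These simulations test the spread between libraries, not the sharing of Mod, since a single comparison is used. That spread is argued against as the cause for the list relative to other genes, while the list's own median depends on the scaling. A weaker hypoxia response with 6-OHG may remain as a hypothesis, with handling, tissue make-up and trends with transcript length that follow the groups left open. The list's call ended without genes under 5 FPKM (adjusted p = 0.313), and its adjusted p = 0.123 with an estimated correlation.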

How the results depend on the processing

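The removal of the length and GC trend, the added components and the fit without the 2 libraries least like their groups were chosen after the data were seen, and all other alternatives were planned. The 28 settings counted here all tested lists with camera at the preset correlation, and leave out the estimated correlation and fry. Over these settings the 37 called lists gave 1033 comparisons, of which 965 kept direction and call, 68 kept direction alone and 0 turned direction. Within these settings 20 of the 37 calls held throughout. For 192 changes of named genes, 5073 of 5306 comparisons kept direction and call, 233 kept direction alone and 0 turned. These changes were picked among called ones and include the largest, so their stability does not stand for all calls. Of all genes called in Mod against Con, 6-OHG against Mod and 6-OHG against Con, removal of the trend left 91.0%, 36.7% and 79.5% called the same way. With the replicate block too it left 61.1%, 3.43% and 65.1%. Counts moved by over 1.5 times as follows, and the cause was not tested unless given. Without a filter 20 lists were called in 6-OHG against Con and 302 genes were reversed. With a filter at 5 FPKM, which tests fewer genes, 2061 genes were called in Mod against Con and 2663 in 6-OHG against Con, and 8 lists in Mod against Con. Sample weights gave 958 reversed genes. A minimum change of 1 left 120, 21 and 131 genes in Mod against Con, 6-OHG against Mod and 6-OHG against Con by construction. An estimated correlation left 1, 0 and 1 lists, and fry called 19 lists in 6-OHG against Con. Removal of the trend gave 992 genes in 6-OHG against Mod and 271 reversed. The first residual component gave 3554 and 1073, a term that cannot carry group differences by construction and only lowers the residual spread. The component of the cell type and region lists gave 930 reversed genes, and the fit without 2 libraries 958.

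With the replicate number as a block, 2039 genes were called in Mod against Con, 846 in 6-OHG against Mod and 181 reversed. With the trend also removed these were 2138, 74 and 25, with 6 lists in 6-OHG against Mod. The numbers do not pair the samples as far as the values show: residuals of 3 of 12 pairs with the same number correlated above 0.1 (-0.48 to 0.35), and 3 of 13 samples correlated best with their own number. The block drops Mod replicate 5, which has no partner.

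Leaving out 1 library at a time gave 2382 to 3653 genes in Mod against Con, 1357 to 2345 in 6-OHG against Mod and 3427 to 4238 in 6-OHG against Con. Lists called were 12 to 16, 7 to 13 and 12 to 17, and reversed genes 317 to 608. Moves beyond 1.5 times were 1357 genes without 6-OHG replicate 4, 7 lists without 6-OHG replicate 1, and 347, 343 and 317 reversed genes without Mod replicate 2, Mod replicate 3 and 6-OHG replicate 4. On a rough measure depth differed by 1.12 times at most, and since counts were not given, what it limits at low values was not measured.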

Other observations

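Genes of the unfolded protein and integrated stress response moved apart in Mod against Con: 6 of 26 were higher and 11 lower (6 and 12 adjusted over the list alone), and the list was not called (adjusted p = 0.104). Ppp1r15a, which ends the block of translation, rose from 3.11 ± 0.411 to 5.18 ± 0.288 FPKM, while the chaperone gene Calr fell from 111 ± 7.35 to 72.2 ± 4.41 FPKM. Both kept these directions in 6-OHG against Con, with log2 changes of 0.65 and -0.86. Cd93, among the 12 largest rises there, rose from 1.36 ± 0.137 to 7.48 ± 1.74 FPKM, while the endothelium list was not called (adjusted p = 0.980).

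Rbm3 and Cirbp are genes that cells induce in mild cold. Rbm3 was chosen after its values were seen, and the test on Cirbp was set after the rise of Rbm3 and before the values of Cirbp were examined. Rbm3 rose from 14.7 ± 1.18 to 37.3 ± 2.00 FPKM in Mod (log2 change 1.28). If lower brain temperature were the cause, Cirbp would rise too, and it rose by 0.95 on the log2 scale (adjusted p = 0.000223). A lower temperature during exposure may therefore contribute, but the labels give no temperature, and low oxygen itself was not separated from cold.

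Other assignments of the libraries to groups were tried for the counts of called genes. For Mod against Con 1 of 100 splits, the real one, gave as many as 3304 genes, with 620 as the highest of the others. For 6-OHG against Mod it was 1 of 100, with 2131 genes against at most 108. For 6-OHG against Con it was 1 of 35, with 4268 against at most 8. The real assignment gave the highest count in all 3 comparisons, which argues against chance assignment as far as these splits go. For 6-OHG against Con 1 of 35 is the least that could be seen. In the other splits the real difference between groups adds to the spread. Their low counts thus do not show how many genes chance alone would call. Any difference in handling that follows the groups stays open.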
